A study of Homo sapiens with 6 samples.

How the data were processed

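Gene expression was measured on 6 Affymetrix whole-transcript arrays, 1 array per sample. The samples were cultured human mesenchymal stem cells from bone marrow, 3 transfected with control siRNA and 3 with siRNA against MED31. RNA was collected 72 h after transfection, and per the labels' protocols 250 ng of total RNA was converted to biotin-labelled sense-strand DNA. The array model and the siRNA sequences were not given in the sources used here.

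The deposited per-array values are log2 signals made by the authors with robust multi-array averaging (RMA), which corrects background, equalises the distribution of probe signals between arrays and summarises the probes of each transcript cluster. The submitters' processing notes name RMA, Affymetrix Expression Console 1.4.1.46 and Transcriptome Analysis Console 4.0. A transcript cluster is the set of probes that the array's annotation assigns to 1 locus. The authors' second deposited table holds their own comparison of the groups. Per the file headers it gives a bi-weight average log2 signal and a standard deviation per group, a signed linear fold change (used here as a score), an ANOVA p-value and an FDR p-value for each of 67528 transcript clusters. It was used for annotation and description only, and its standard deviations were not used. RMA sets the arrays to a common distribution, so a change of the same size in all RNAs would not appear in these values. Signals near the background are compressed, and small fold changes of dim genes are therefore understated.

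The per-array table held 70523 features. The 2995 features outside the authors' comparison table were control probes and were not tested as genes. Of the remaining clusters, 38466 carried exactly 1 gene symbol, 4469 carried several and 24593 carried none, and only clusters with 1 symbol were named. Symbols were updated with a RefSeq gene table: 28465 were current, 1637 were renamed through a RefSeq accession, 691 through a synonym, and 7673 kept the symbol of the file. Y-linked genes, XIST and TSIX (121 clusters) were left out because the cells are primary human cells. Where a gene had several clusters (5799 genes), the cluster with the highest mean over all 6 arrays was used. This gave 30930 genes, of which the 15465 with a mean log2 signal of at least 5.35, the median over these genes, were tested. The genome build was not named in the sources used here. Of the clusters with a GRCh37 transcript position in the annotation, 49.1% shared a start or end with the cluster's own position, against 0.6% for GRCh38, so coordinates are given as GRCh37.

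The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the deposited log2 values, without covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are limma's moderated ones. The smallest p of an exact permutation test of 3 against 3 samples is 0.1, so single values cannot pass 0.05 in that test. The labels do not say that the samples came from separate cultures or donors. The p-values therefore measure the spread between these samples, which may be technical. For arrays no read depth applies, and the number of arrays limits the precision.

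Before the data were examined, 48 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 46 lists with at least 5 tested members were compared with all other tested genes by limma's camera, with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a set's genes move on balance one way, and its mixed version whether they change in either direction; neither compares the set with other genes. The named genes were MED31 and its neighbours TXNDC17 and C17orf100, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 4 members per described list with the smallest p. Symbols that start with LOC, LINC, MIR, SNOR, RNU or RN7, or with RP, digits and a dash, symbols containing -AS, and symbols that are only accessions were passed over in the lists of largest changes. The rule goes by symbol, so RNVU1-15, a small nuclear RNA with another prefix, was kept. Near-identical copies cannot be separated with certainty by array probes, so BNIP3 and its pseudogene BNIP3P1, KRT14 and KRT17, the histones and the small nuclear RNAs are uncertain individually.

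The alternatives were quantile normalization, median centring, no or a stricter brightness filter (log2 signal of 7.56), a trended robust variance, array weights, a plain t-test per gene, fold thresholds of 1.5 and 2, the mean of a gene's clusters, all clusters, the replicate number as a block, and each array left out. Overrepresentation of annotation terms, with terms of 10 to 500 genes from the authors' annotation columns, was added after the data were seen. The comparison was tested on simulated data with 200 changed genes among 15465 in each of 20 simulations. It recovered 12.5% of 1.25-fold, 79.0% of 1.5-fold and 95.9% of 2-fold changes, and 5.1% of the calls were false. The simulated noise was independent between genes, so these shares may not hold where genes vary together. The data gave 1668 calls, more than the 200 changed genes of a simulation. The Benjamini-Hochberg cutoff depends on the share of changed genes, so the recovery of small changes in the data may differ. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.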

Results

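Transcript levels were compared between bone-marrow mesenchymal stem cells (MSCs) that received control siRNA (n = 3) and MSCs that received siRNA against MED31 (n = 3). MSCs are stromal cells that can form bone, cartilage and fat cells. MED31 is a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. The comparison asked which genes change in undifferentiated MSCs 72 h after MED31 is depleted. Median signals over all features lay between 5.01 and 5.08 (log2) on the 6 arrays. Across the 15465 tested genes, correlations between arrays were 0.9941 to 0.998 within groups and 0.9894 to 0.9939 between groups. The first principal component held 50.1% of the variance and separated the groups.

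MED31 itself fell to 33.3% of its control level. Its log2 signal was 9.10, 9.10 and 9.38 in the control arrays (mean 9.19 ± 0.16 SD, n = 3) and 7.43, 7.51 and 7.87 in the MED31 siRNA arrays (mean 7.60 ± 0.24 SD, n = 3). This is a log2 change of -1.59 (SE 0.14, limma adjusted p = 0.00226), and the exact two-sided permutation p was 0.1, the smallest that 6 samples allow. The MED31 cluster (TC17001066.hg.1) spans the gene on the minus strand of chromosome 17, from 6546633 to 6554954 (GRCh37). The position of the siRNA target in the transcript was not given in the sources used here. TXNDC17, a thioredoxin-related gene on the opposite strand (6544078 to 6547920) whose locus overlaps that of MED31, had a log2 change of -0.11 (SE 0.12, adjusted p = 0.574). C17orf100, on the other side of MED31 (6554971 to 6556617), was below the brightness filter, with a log2 change of 0.24 (SE 0.11, adjusted p = 0.312 in the fit without the filter).

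Over the whole transcriptome 1668 of 15465 genes changed, 797 upward and 871 downward, and 4295 had an unadjusted p under 0.05. The balance of directions depended on scaling and arrays: 1059 rose and 844 fell with median centring, 1050 and 934 with quantile normalization, and 496 and 823 without MED31 siRNA replicate 3. Most changes were small. The median absolute log2 change of the called genes was 0.42, and 17 genes rose and 41 fell by at least 2-fold. With each gene's clusters averaged, 9 called genes rose and 36 fell by at least 2-fold. The groups did not overlap for any called gene, and they did not overlap for 35% of all tested genes, where chance gives 10%. Fewer genes were called with 1 array left out, where power is also lower. The number was 993, 537 and 634 without control replicates 1, 2 and 3, and 546 without MED31 siRNA replicate 1. Of those 537, 634 and 546 calls, 528, 615 and 538 were among the 1668.

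The largest rise was that of B3GALT2, a galactosyltransferase, by 1.64 on the log2 scale (SE 0.08, adjusted p = 0.000873). JAG1, a Notch ligand, rose by 1.53 (SE 0.07, adjusted p = 0.000843), and PAPPA, a protease that cleaves IGF-binding proteins, by 1.40 (SE 0.13, adjusted p = 0.0024). KRT14, a keratin of basal epithelial cells, rose by 1.47, the stress-induced cytokine GDF15 by 1.31, and the stem cell factor receptor KIT by 1.21. The vitamin D receptor VDR rose by 1.21, dystrophin (DMD) by 1.20, USP53, of the ubiquitin-specific protease family, by 1.18, and the hyaluronan-binding protein TNFAIP6 by 1.17. The DMD value is that of 1 of its 5 clusters, from 31241147 to 31285069 on the X chromosome. Adjusted p of these 10 genes reached at most 0.0109. Without control replicate 2 or MED31 siRNA replicate 1 GDF15 no longer passed (log2 changes of 1.26 and 1.24). TNFAIP6 did not pass when its clusters were averaged (0.78).

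The largest fall was that of STC1, which encodes the secreted glycoprotein stanniocalcin 1, with a log2 change of -1.85 (SE 0.12, adjusted p = 0.00125). After MED31 came INHBB, a subunit of activin B (-1.51, SE 0.11, adjusted p = 0.00152), and the carboxypeptidase CPA4 (-1.44, SE 0.06, adjusted p = 0.000843). PFKFB3, which sets the level of an activator of glycolysis, changed by -1.42, and SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, by -1.37. The siRNA sequence was not given in the sources used here, so a direct action of the siRNA on SEC23A or other transcripts was not tested. BNIP3, a mitochondrial protein of mitophagy, and its pseudogene BNIP3P1, whose probes may share signal, changed by -1.30 and -1.31. A variant U1 small nuclear RNA, RNVU1-15, changed by -1.30 and filaggrin (FLG) by -1.28. Another 4 small RNA symbols were passed over in this ranking. The FLG value is that of 1 of its 4 clusters, from 152286184 to 152286725 on chromosome 1. FLG did not pass without MED31 siRNA replicate 1 (-1.27), while 18 of the 20 genes with the largest changes passed with each array left out in turn.

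**Figure D1:**
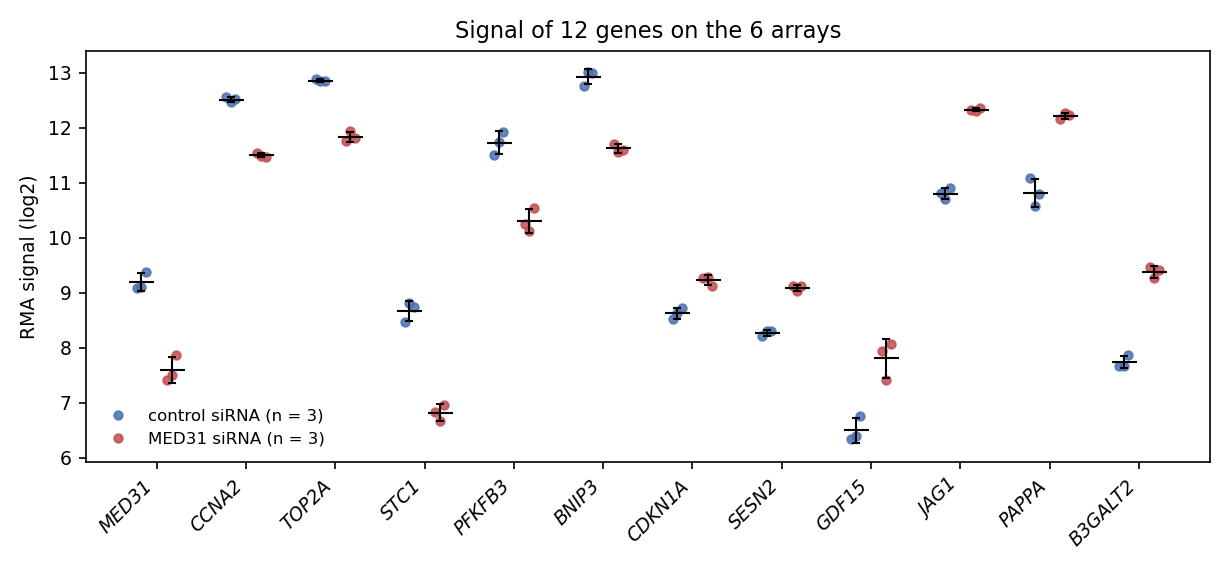
RMA signal (log2) of 12 genes on each array. Points are arrays, horizontal lines are group means and bars are standard deviations (n = 3 per group). For every gene drawn, the 3 MED31 siRNA arrays lie on one side of the 3 control arrays.

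Genes of cell division fell together. Of 70 tested G2/M and mitosis genes, 64 fell, none rose and 6 did not pass, and all 70 had lower means after MED31 siRNA. Adjusted over the list alone, 68 fell. Members with the smallest p included CCNA2, the cyclin of S phase and mitotic entry (-1.01, SE 0.05), topoisomerase TOP2A (-1.02, SE 0.06) and the spindle regulator DLGAP5 (-0.86, SE 0.05). The median log2 change was -0.64 (camera adjusted p = 3.14e-45, and adjusted p = 0.0403 with an estimated correlation). This was the only list of 46 whose call held with an estimated correlation.

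Of 54 DNA replication and G1/S genes, 33 fell, none rose and 21 did not pass, and 46 fell when adjusted over the list alone. The nucleotide synthesis enzymes TYMS and RRM2 changed by -0.68 (SE 0.05) and -0.85 (SE 0.08), the chromatin assembly factor CHAF1B by -0.55 and the replication factor MCM10 by -0.50. The median was -0.38 (camera adjusted p = 1.39e-19, and adjusted p = 0.111 with an estimated correlation). The count of falls was 13 and 16 without control replicates 2 and 3, and 15 without MED31 siRNA replicate 1. Among 47 DNA repair genes, 12 fell, 1 rose and 34 did not pass; adjusted over the list alone, 16 fell and 1 rose. The falls included FANCI (-0.56), BRCA1 (-0.70) and BRCA2 (-0.54), and the 1 rise, named after its value was seen, was the helicase ERCC2 (0.62). The median was -0.13 (camera adjusted p = 6.79e-05, and adjusted p = 0.494 with an estimated correlation). That count of falls was 7, 5 and 6 without control replicates 1, 2 and 3, and 4 and 7 without MED31 siRNA replicates 1 and 2. ERCC2 did not pass without any one of the 3 control arrays or without MED31 siRNA replicate 1, and no gene of that list rose with clusters averaged. Of 12 replication-dependent histone genes, the linker histones H1-1 (-0.99) and H1-5 (-0.58) fell and 10 did not pass (5 falls adjusted over the list alone; median -0.47, camera adjusted p = 0.00206, and adjusted p = 0.609 with an estimated correlation). Only 1 histone fell without control replicate 2, control replicate 3 or MED31 siRNA replicate 1, while 5 fell without MED31 siRNA replicate 3. The groups overlapped by array in the mean of this list, which deviated from the control mean by -0.26, 0.13 and 0.14 in the control arrays and by -0.60, -0.65 and -0.22 in the MED31 siRNA arrays.

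Glycolysis and hypoxia response genes were lower. Of 35 tested, 21 fell, 1 rose and 13 did not pass, and 25 fell and 1 rose when adjusted over the list alone. PFKFB4, a relative of PFKFB3, changed by -0.91 (SE 0.06), BNIP3 by -1.30 (SE 0.08), the enolase ENO2 by -1.24 (SE 0.09) and NDRG1, a gene induced by low oxygen, by -0.63 (SE 0.05). The rise was in the glucose transporter SLC2A3 (0.36), named after its value was seen, which did not pass without control replicates 2 or 3 or MED31 siRNA replicate 1. The median was -0.37 (camera adjusted p = 6.62e-13, and adjusted p = 0.111 with an estimated correlation). The falls numbered 12 and 11 without control replicates 2 and 3, and 12 without MED31 siRNA replicate 1.

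Targets of p53, the transcription factor of the DNA damage response, were higher. Of 33 tested, 18 rose, 2 fell and 13 did not pass, and 27 rose and 3 fell when adjusted over the list alone. The stress sensor SESN2 rose by 0.82 (SE 0.06), SPATA18 by 0.95 (SE 0.07), the death receptor TNFRSF10B by 0.76 (SE 0.06) and GADD45A by 0.56 (SE 0.05). The genes that fell, named after their values were seen, were MDM2 (-0.42, adjusted p = 0.0217), whose product marks p53 for degradation, and INKA2 (-0.75, adjusted p = 0.0364). Neither of these passed without control replicate 2 or MED31 siRNA replicate 2, and only 1 gene of the list fell without any other array. The median was 0.35 (camera adjusted p = 5.61e-13, and adjusted p = 0.189 with an estimated correlation). Without control replicate 2 or MED31 siRNA replicate 1, 10 rose. Among 16 CDK inhibitors and D cyclins, CDKN1A (0.60), CDKN2B (0.61) and CCND1 (0.27, named after its value was seen) rose and RBL1 (-0.56) and CDK6 (-0.49) fell, with 11 not passing and no shift of the list (camera adjusted p = 0.384). CDKN2B did not pass without MED31 siRNA replicate 1, nor CDK6 without control replicate 3 or MED31 siRNA replicate 1, and CCND1 did not pass with any array left out.

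Genes of the amino acid response, driven by the factor ATF4, were also higher: 15 of 39 rose, 2 fell and 22 did not pass, and 28 rose and 3 fell when adjusted over the list alone. Besides SESN2, which is also in the p53 list, they included PHGDH, the first enzyme of serine synthesis (0.41), the stress factor DDIT3 (0.50) and STC2 (0.43). The falls, named after their values were seen, were the amino acid transporter SLC38A2 (-0.26) and DDIT4 (-0.39), which is also in the hypoxia list; only 1 gene of the list fell without MED31 siRNA replicate 2, and none without any other array. The median was 0.25 (camera adjusted p = 5.46e-09, and adjusted p = 0.189 with an estimated correlation). Without control replicate 2, control replicate 3 or MED31 siRNA replicate 1, the rises numbered 5, 9 and 5, and without control replicate 2 STC2 did not pass. Of 40 interferon-stimulated genes 11 rose, none fell and 29 did not pass (15 rose when adjusted over the list alone). They included the RNA sensor RIGI (0.85, SE 0.09), IFI27 (1.02, SE 0.13), GBP1 (0.47) and STAT2 (0.56). The median was 0.29 (camera adjusted p = 5.42e-09, and adjusted p = 0.494 with an estimated correlation). This count was 5 without control replicate 2, 5 without control replicate 3, and 4, 7 and 6 without MED31 siRNA replicates 1, 2 and 3. The mean of the interferon list was 0.10 and 0.06 above the control mean in control replicates 1 and 2, and its deviation in control replicate 3 was -0.17.

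**Figure D2:**
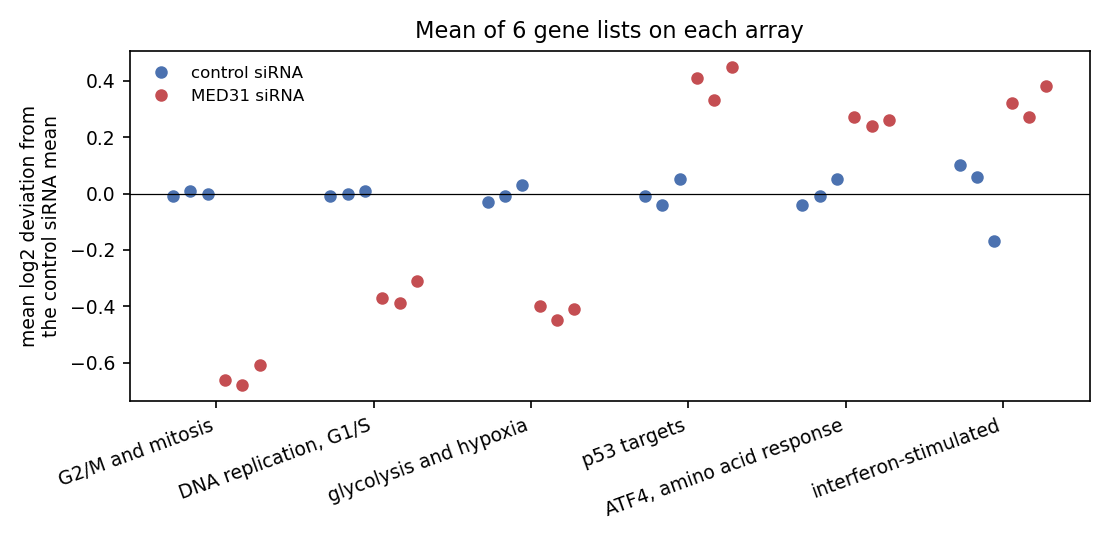
Mean log2 deviation of 6 gene lists from the control siRNA mean, with each point being 1 array. The G2/M list lies between -0.68 and -0.61 on the MED31 siRNA arrays, and the p53 list between 0.33 and 0.45.

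The camera test with the preset correlation called 18 of 46 lists, 12 upward and 6 downward. Fry passed 13 of these 18, not those for other matrix genes, histones, immediate early genes, lysosome and RNA polymerase II, and it also passed the adipogenic, epithelial and Notch and Hedgehog lists. Besides the leading 6 (G2/M, G1/S, hypoxia, p53, ATF4 and interferon), the other 12 called lists included DNA repair and histones. In these 12, 43 of 362 genes rose and 28 fell. These 71 changed genes numbered 42, 27 and 33 without control replicates 1, 2 and 3, and 28 without MED31 siRNA replicate 1. Of 34 TGF-beta and BMP genes, 6 rose, 1 fell and 27 did not pass (7 and 1 adjusted over the list alone), but 2, 3 and 2 rose without control replicate 2, control replicate 3 and MED31 siRNA replicate 1, and 2 fell without MED31 siRNA replicate 3. The ligand TGFB2 (0.98) and the BMP antagonist GREM1 (0.55) rose, and the hypoxia-responsive repressor BHLHE40 (-0.56) fell; the median was 0.13 (camera adjusted p = 0.00114, and adjusted p = 0.494 with an estimated correlation). Among 41 lysosome and autophagy genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the sialidase NEU1 (0.41) and prosaposin PSAP (0.31) among the rises; only 1 rose without any one control array or without MED31 siRNA replicate 1, and 3 without MED31 siRNA replicate 3, and none fell without any array other than that one (camera adjusted p = 0.00114, and adjusted p = 0.609 with an estimated correlation). Of 38 RNA polymerase II and general transcription factor genes, 5 rose (5 adjusted over the list alone), led by the largest polymerase subunit POLR2A (0.79), but only 1 without any array other than MED31 siRNA replicate 3, and 3 without that one (camera adjusted p = 0.00416, and adjusted p = 0.609 with an estimated correlation). In 35 smooth muscle and actin genes, 5 rose and 3 fell (11 and 3 adjusted over the list alone), including the contractile proteins CNN1 (0.65), LMOD1 (0.72) and ACTA2 (0.57) and non-muscle myosin MYH10 (-1.01; camera adjusted p = 0.0185, and adjusted p = 0.494 with an estimated correlation). In that list 3 rose without control replicate 1, control replicate 2 or MED31 siRNA replicate 3, and 1 fell without any array other than MED31 siRNA replicate 3. In 39 other matrix genes 5 rose (6 adjusted over the list alone), with the proteoglycans LUM (0.70) and DCN (0.43; camera adjusted p = 0.0342, and adjusted p = 0.658 with an estimated correlation). Of these, 3, 1 and 2 rose without control replicates 1, 2 and 3, and 2 and 3 without MED31 siRNA replicates 1 and 3. DCN did not pass without control replicate 2 or MED31 siRNA replicate 1, or with its clusters averaged (0.24). Of 28 metalloproteinases and inhibitors 5 rose and 1 fell (5 and 1 adjusted over the list alone), including ADAMTS2 (0.61) and MMP16 (0.75; camera adjusted p = 0.0271, and adjusted p = 0.494 with an estimated correlation). Of these 3 rose without control replicate 2, control replicate 3 or MED31 siRNA replicate 1, and none fell without any array other than control replicate 1.

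The remaining 4 called lists held members that moved both ways or few calls. Of 33 apoptosis regulators, 7 rose and 2 fell (8 and 3 adjusted over the list alone); BCL2L1, which blocks apoptosis, rose by 0.73, and APAF1, which promotes it, had a change of -0.76 (camera adjusted p = 0.0381, and adjusted p = 0.494 with an estimated correlation). The rises numbered 3, 4 and 3 without control replicate 2, control replicate 3 and MED31 siRNA replicate 1. In 32 immediate early genes JUNB (0.47) and SRF (0.45, named after its value was seen) rose, and EGR1 (-1.17), KLF6 (-0.35) and JUN (-0.49) fell (3 and 3 adjusted over the list alone). No gene of this list rose without any array other than MED31 siRNA replicate 2, and JUN and KLF6 each passed with only 1 array left out at a time (JUN without MED31 siRNA 3, KLF6 without control 3). By array the groups overlapped, with mean deviations of -0.09, 0.03 and 0.06 in the control arrays and 0.07, -0.05 and 0.20 in the MED31 siRNA arrays. The list median was 0.15 (camera adjusted p = 0.0385, and adjusted p = 0.776 with an estimated correlation). In 23 YAP/TAZ targets 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0452, and adjusted p = 0.658 with an estimated correlation), but 1 rose and none fell without control replicate 2, control replicate 3 or MED31 siRNA replicate 1, and 2 rose without MED31 siRNA replicate 3. Of 8 neural markers ENO2, which is also a glycolysis gene, and the neurofilament NEFM (-0.44) fell (3 adjusted over the list alone; camera adjusted p = 0.038, and adjusted p = 0.467 with an estimated correlation). The calls of the 6 leading lists held with each array left out, while 6 of the other called lists lost theirs, at adjusted p between 0.0505 and 0.241. They were apoptosis (without control replicates 1 and 2 and MED31 siRNA replicates 2 and 3), immediate early genes (control 1, MED31 siRNA 3) and YAP/TAZ targets (control 2 and 3, MED31 siRNA 3), together with neural markers (control 2, MED31 siRNA 3), metalloproteinases (control 1) and other matrix genes (control 2). These 6 lists and the smooth muscle list also lost their calls under quantile normalization.

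**Figure D3:**
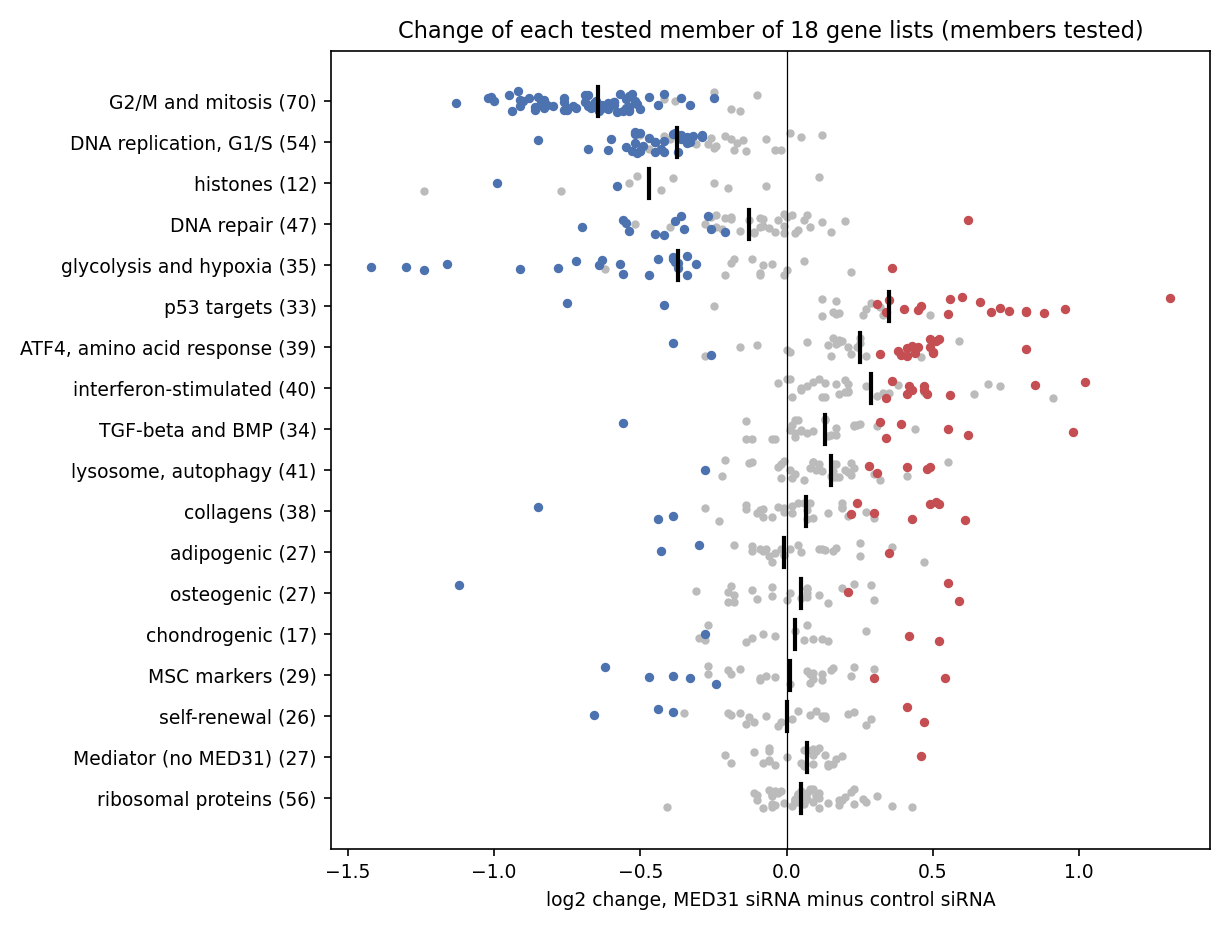
Log2 change of every tested member of 18 gene lists, with the number of members in brackets. Red and blue points are genes that rose and fell at an adjusted p under 0.05, grey points did not pass, and black bars are medians (-0.64 for G2/M, 0.35 for p53 targets).

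Genes of the MSC lineages changed individually, with no shift of any lineage list by camera. Of 27 osteogenic genes, 3 rose and 1 fell (5 and 3 adjusted over the list alone). ENPP1, which makes the mineralisation inhibitor pyrophosphate, changed by -1.12 (SE 0.06), GREM1 by 0.55 and TNFRSF11B, the decoy receptor that restrains osteoclasts, by 0.59 (camera adjusted p = 0.594). Of 27 adipogenic genes, ZNF423 rose (0.35) and the desaturase SCD (-0.30) and EBF2 (-0.43) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.532, fry adjusted p = 0.0146). Of 17 chondrogenic genes, the cartilage matrix genes MATN3 (0.52) and FMOD (0.42) rose and HAS2 (-0.28), a hyaluronan synthase, fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.751). Together 10 genes of the 3 lists changed, against 5, 4 and 6 without control replicates 1, 2 and 3, and 4 without MED31 siRNA replicate 1. SCD did not pass with any array left out, EBF2 passed only without control replicate 3, FMOD only without control replicate 3 or MED31 siRNA replicate 2, and HAS2 only without MED31 siRNA replicates 2 or 3. ZNF423 did not pass without control replicates 2 or 3 or MED31 siRNA replicate 1.

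Among 29 MSC surface and culture markers, 2 rose, 5 fell and 22 did not pass (3 and 7 adjusted over the list alone). The integrin ITGA5 rose by 0.54 and the tetraspanin CD81 by 0.30, and the adhesion molecules ALCAM (-0.62) and CD44 (-0.47) were among the falls (camera adjusted p = 0.597). Without control replicate 2, control replicate 3 and MED31 siRNA replicate 1, 2, 2 and 3 fell and 1 rose each time. Of 26 pluripotency and self-renewal factors, 2 rose, 3 fell and 21 did not pass (5 and 4 adjusted over the list alone). The histone methyltransferase EZH2 (-0.44), the DNA methyltransferase DNMT1 (-0.39) and the cytokine LIF (-0.66, named after its value was seen) fell, and JARID2 (0.41) and FOXO3 (0.47) rose (camera adjusted p = 0.937). The 12 changed genes of both lists numbered 4 and 5 without control replicates 2 and 3, and 7 without MED31 siRNA replicate 1. CD81 and DNMT1 did not pass without control replicates 2 or 3 or MED31 siRNA replicate 1, FOXO3 without any one control array, and JARID2 without control replicate 2. LIF did not pass without control replicates 2 or 3 or MED31 siRNA replicates 1 or 2, while 6 genes of this list fell without MED31 siRNA replicate 3. Of 27 tested Mediator subunits other than MED31, only MED15 passed (0.46, adjusted p = 0.0442; 0 adjusted over the list alone), a call lost without control replicates 1, 2 or 3 or MED31 siRNA replicates 1 or 3 and with its clusters averaged (0.32; camera adjusted p = 0.371).

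In the authors' deposited table, 140 of 67166 clusters had a p under 0.05 and a fold change of at least 2, 34 upward and 106 downward, and 141 had an FDR under 0.05. That deposited table lists MED31 with a fold change of -3.04 and an FDR of 0.0875.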

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

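The tests of RNA families and of signal brightness and the count of sample splits were chosen only after the results they bear on were seen, as was the choice of the patterns weighed here. The small RNA classes and the additional hypoxia genes were chosen after the changes of the whole transcriptome were seen.

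Clusters without exactly 1 gene symbol were outside the comparison of genes, and a signal appeared there too. In a fit of 27478 clusters, 75 of 9209 such clusters were called higher, in all 3 MED31 siRNA arrays, than in the 3 control arrays, and 220 were called lower. The largest log2 changes were 1.40 and -2.84. Together 3.2% of them changed, against 6.5% of clusters with 1 symbol.

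Small nuclear RNAs made by RNA polymerase II, with the nucleolar RNA U3, had a median log2 change of -0.39 over 192 tested symbols, of which 48 fell and none rose; 166 of them are pseudogene symbols, and the other 26 had a median of -0.72. A lower recovery of all small RNA in the MED31 siRNA samples is argued against by 175 small nucleolar and Cajal body RNAs processed from introns, whose median was -0.05 (permutation p = 1e-05 over genes, the smallest that the permutations can give; copies of a family are not independent). Cross-hybridization within a single RNA family is argued against by 5 of 9 families with a median below -0.3, U3 at -1.22 and U5 at -0.59 among them. Most falls were in U1 (28 of 69), U2 (10 of 19) and U3 (4 of 4). U4 had 3 of 27, U4atac 1 of 6, U5 1 of 12 and U7 1 of 52. The medians of U7 (-0.15), U11 (-0.15) and U8 with U13 (-0.02) were nearer to no change. Cross-hybridization within each of several families was not tested. Whether small RNAs of polymerase III took part cannot be told apart, since their median of -0.18 lies close to 0.5 of the polymerase II median (bootstrap 95% interval of the gap -0.016 to 0.053). Their median differed from that of the polymerase II class (permutation p = 1e-05 over genes), but 699 of these 894 symbols had a change below 0. Pseudogene symbols made up 880 of the 894, and the other 14 had a median of -0.02. A lower level of some families of polymerase II small RNAs after MED31 loss may therefore be one hypothesis. Differences in RNA recovery by length within the classes were not tested.

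The fall of the glycolysis and hypoxia list is not a matter of signal brightness: its median of -0.37 stood at percentile 0 of 10000 random lists matched on mean signal, whose central 95% ran from -0.05 to 0.10. Hypoxia-induced genes outside the list had a median of -0.15 over 31 tested, at percentile 0.03 of matched lists, and 11 fell and 1 rose. The camera p of this set within limma was 7.16e-06 and 0.0606 with an estimated correlation. Lower hypoxia-inducible transcription as a whole may explain both sets. Cell density and oxygen in the cultures could likewise differ between the groups, and the labels do not record them.

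The fall of the mitosis list was also not explained by brightness, with its median of -0.64 at percentile 0 of matched lists (central 95% from -0.03 to 0.08). No single array carried it, since the least negative median with 1 array left out was -0.62. A hypothesis is that fewer cells were dividing after MED31 siRNA, which may be a consequence of MED31 loss or of an siRNA effect unrelated to it. With only a control siRNA group and a MED31 siRNA group these stay open.

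Of the 10 splits of the 6 arrays into 3 and 3, only the real split (1 of 10) reached 1668 genes, and the highest of the others gave 0 by limma, with 176 to 893 genes at an unadjusted p under 0.05 against 4295. With 10 splits the share cannot fall under 0.05.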

How the results depend on the processing

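Per-array values of the other deposited table were not run because it holds group averages. The MED31 level kept its direction and its call under each alternative run for it (quantile normalization, median centring, the robust variance, averaged clusters, the replicate block and each array left out), with log2 changes from -1.72 to -1.49. The count of changed genes (1668) stayed within 1.5 times under quantile normalization (1984), median centring (1903), a stricter filter (1810), a trended robust variance (1764), averaged clusters (1592) and all clusters (1480). It was 802 without a brightness filter, where 30930 genes share the correction, 888 with a plain t-test and 4602 with array weights. The weights ran from 0.38 to 3.99, the highest on MED31 siRNA replicate 1. By construction fewer genes passed with an added 1.5-fold limit (400), and 63 passed with an unadjusted p and a 2-fold limit together. With 1 array left out the count ranged from 537 to 1358, with fewer samples. With the replicate number as a block it was 719, of which 686 were among the 1668. Deviations of same-numbered arrays correlated at -0.17, 0.04 and 0.04, and not every array correlated best with its own number. These correlations gave no sign that the numbers pair the samples. They cannot exclude pairing, because each group holds few arrays and deviations were taken within the groups. The labels do not say whether same-numbered samples share a culture or day. The 322 changed list members became 203 without the filter, 571 with array weights, 203 with a plain t-test, 189 with the replicate block, and 157 to 266 with 1 array left out. The 18 called lists became 11 under quantile normalization and 1 with an estimated correlation. With it the G1/S (median -0.38), p53 (0.35), hypoxia (-0.37), ATF4 (0.25) and interferon (0.29) lists lost their calls. The cause was not tested where none is named. Of 146 genes picked by the rule for named genes over all lists (MED31 not counted), none reversed. Genes named after their values were seen were outside this count. Calls were lost by 2, 5, 2 and 7 of the 146 under quantile normalization, median centring, the robust variance and averaged clusters. The block ended 40 calls and leaving out an array 19 to 50. Signals of the 92 spike-in features, near background, had medians of 4.34, 4.46 and 4.41 in the control arrays. They were 4.58, 4.54 and 4.49 in the MED31 siRNA arrays, a difference whose cause was not tested. Background probes had array medians of 3.69 to 3.98, below the filter of 5.35, so dim genes at the filter still had room to fall.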

Other observations

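The enrichment tests here were chosen only after the data were seen, as one-sided tests of overrepresentation against tested genes with an annotation. Among genes that rose, cell adhesion held 43 of its 283 genes where 18.6 were expected by chance (adjusted p = 0.00019 over 1117 terms). Extracellular matrix organization held 27 of 174 (adjusted p = 0.00891), with the matrix proteins LUM (0.70) and COL8A1 (0.52) among them. Some changed members of both terms fell, such as MYH10 (-1.01) in cell adhesion, PLOD2 (-0.85) in matrix organization and ITGA4 (-0.89) in each. Female pregnancy held 10 of 32 (adjusted p = 0.00891), with PSG5 (1.08), PSG1 (1.09), PSG9 (0.90) and PAPPA (1.40). The PSG genes are near-identical copies whose probes may share signal, which was not tested. Among genes that fell, glycolytic process held 11 of 27 (adjusted p = 8.03e-06), mitotic cell cycle 90 of 319 (adjusted p = 2.31e-36) and centromere-specific nucleosome assembly 10 of 21 (adjusted p = 5.36e-06). The 11 include CDCA3 (-0.42), which the annotation also places under cell adhesion and extracellular matrix organization, so some term assignments may be wrong. In all 6 biological process terms passed among rises and 40 among falls. Genes of a term are not independent.

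Lists without a camera call (28 of 46, adjusted p from 0.11 to 0.937) held 99 changed genes of 685, against 73, 41, 48, 44, 82 and 77 with each array left out in turn, control replicates 1 to 3 first. Of 13 epithelial markers, 7 had higher and 6 lower means, with a median of 0.07 (camera adjusted p = 0.11, adjusted p = 0.494 with an estimated correlation, fry adjusted p = 0.00423). KRT14 (1.47), KRT19 (0.88), KRT7 (0.40) and KRT17 (0.24) rose, 4 adjusted over the list alone, and KRT7 and KRT17 lost their calls with any of the 6 arrays left out. KRT7 also lost its call with its clusters averaged (0.17). Of 11 haematopoietic markers only KIT rose, of 7 endothelial markers only TEK (0.27, a call lost with any array left out), and of 12 skeletal muscle markers none changed. Of 4 tested erythroid markers, too few for a list test, TFRC fell (-0.76). Among 17 commonly used reference genes, YWHAZ (-0.49), TFRC and HPRT1 (-0.42) fell and POLR2A (0.79) and B2M (0.32, named after its value was seen) rose. In 5 of the lists without a call the median, the mean and the test differ in sign: adipogenic (-0.01, 0.03, higher), endothelial (-0.01, 0.02, higher), haematopoietic (-0.09, 0.01, lower), MSC markers (0.01, -0.03, lower) and self-renewal (0, -0.01, higher). None of 56 ribosomal protein genes and none of 49 respiratory chain genes passed by limma.

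Of 22 senescence-associated genes 5 fell and 2 rose, with the nuclear lamina gene LMNB1 (-1.03) and SERPINE2 (-0.96) leading the falls (camera adjusted p = 0.565). The list mixes secreted factors and inhibitors of the cell cycle with LMNB1, so its counts do not tell more senescence from less. Only 2 fell without any one of control replicates 2 and 3 and MED31 siRNA replicates 1 and 2. Without MED31 siRNA replicate 3 the falls numbered 3, and at most 1 gene rose with any array left out. Of 19 NF-kB targets 5 rose and 3 fell, among them the prostaglandin synthase PTGS2 (-1.26), TNFAIP6 (1.17) and PTX3 (0.48); 3 rose without any one control array or MED31 siRNA replicate 1, and 1 fell without control replicates 2 or 3. Of 28 Wnt genes 6 rose and 3 fell, with the antagonists DKK1 (0.83) and SFRP1 (-0.98) moving in opposite directions; 3, 1 and 2 rose without control replicates 1, 2 and 3 and 2 without MED31 siRNA replicate 1, and 1 fell without control replicate 2. Of 38 collagen genes 8 rose and 3 fell, with COL4A1 (0.49) and the lysyl hydroxylase PLOD2 (-0.85); 3 rose without control replicate 2 and 4 without control replicate 3 or any one MED31 siRNA array, and 1 fell without control replicates 2 or 3 or MED31 siRNA replicate 1. Of 35 growth factor genes 6 rose and 4 fell, with FGF5 (-0.94) and the receptor MET (0.66). In that list 2, 2 and 1 rose and 2, 2 and 2 fell without control replicate 2, control replicate 3 and MED31 siRNA replicate 1. Of 17 Notch and Hedgehog genes JAG1 and RBPJ (0.24) rose. In the small RNA silencing list DICER1 (-0.84) fell, and in the antioxidant list NQO1 (-0.75) fell while ME1 (0.38) and AKR1C3 (0.30) rose, and 3 genes of that list fell without control replicate 1. Of 41 ribosome biogenesis genes 6 rose and 1 fell, but none changed without control replicate 2, control replicate 3 or MED31 siRNA replicate 1; 4 rose and none fell without control replicate 1, and 4 and 2 rose without MED31 siRNA replicates 2 and 3. Of 29 unfolded protein response genes, 30 heat shock genes and 31 fatty acid genes, few passed and most of these calls were lost with some array left out. RBPJ and AKR1C3 lost their calls with any array left out. B2M did not pass without any array other than MED31 siRNA replicate 2, nor HPRT1 with its clusters averaged (-0.39). Without control replicate 2, SFRP1 (-0.96), HPRT1 (-0.40) and ME1 (0.35) did not pass, nor did ME1 (0.36) without MED31 siRNA replicate 1. A fit with 1 array fewer has less power, so a lost call need not mean reliance on that array.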
